A study of Escherichia coli with 15 samples.

How the data were processed

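RNA of Escherichia coli MG1655 thyA- cells, which cannot make thymidylate and need thymine from the medium, was measured on 15 two-colour arrays. Per the labels, cultures given 20 ug/ml thymine in M9 minimal medium, with glucose at 0.2%, were taken in mid-exponential phase, washed and moved to medium with no thymine (starvation) or with limiting thymine (limitation). The thymine level of the limiting medium is not given in the sources used here. Each array paired RNA from 15, 30, 45, 60 or 90 min after the shift with RNA from before the shift, at 0 min. Starvation had 2 biological replicates at each time, and limitation had 1. Per the labels, starvation replicate 1 held the shifted RNA in Cy3, while starvation replicate 2 and all limitation arrays held it in Cy5.

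The deposited values are log ratios per array, read here as log2 ratios. The base of the logarithm, the normalisation and the background correction are not given in the sources used here, so sizes are given in log units and no fold is derived from them. Whether replicate 1 shares the orientation of replicate 2 was settled from the table by a rule fixed before the data were examined. The 2 starvation replicates correlated above 0 over genes at 4 of the 5 time points (Pearson r of 0.584 at 30 min, 0.0932 at 45 min, 0.497 at 60 min and 0.487 at 90 min) and below 0 at 15 min (r = -0.343). The ratios of replicate 1 were therefore taken as already turned to the orientation of replicate 2, and no sign was changed. The correlation is the same if the whole table is turned. That the ratios are shifted over unshifted RNA was therefore read from the dyes, as Cy5 over Cy3 in replicate 2. The SOS list lay above 0 in both replicates under this reading. Array medians were not 0. They ranged from -0.66 to 0.58 and lay below 0 on all 5 arrays of starvation replicate 2.

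The table held 4293 rows with 0 missing values, of which 4098 had 1 gene symbol, 0 had several and 195 were unnamed. Names were updated through Entrez identifiers in a table of the ASM584v2 assembly, which matched 4097 rows. In 638 rows (14.9%) the values repeated along the 15 columns with a period of 1 to 5 columns, exactly to the last printed digit, once the sign of replicate 1 was turned back. In 568 of these the period was 2. Such rows cannot hold 15 separate measurements. They were left out, a choice made after the data were examined, which leaves 3655 rows, called genes below. The 0 missing values and 0 repeated gene names left 2 intended comparisons (complete genes, single rows) with nothing to change.

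Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the values as deposited, with Benjamini-Hochberg adjusted p under 0.05. The time points of a replicate were averaged, giving 2 culture means, for the starvation mean against 0. In that fit the estimated prior degrees of freedom were infinite, so all genes shared a standard error of 0.33. Single times were fitted over 10 arrays with 5 time means. Late (60 and 90 min) was set against early (15 and 30 min) over 8 arrays, taken as independent although they come from 2 cultures. Starvation minus limitation was fitted over 3 culture means, with the lone limitation culture assumed to vary like the starvation cultures. Limitation alone was not tested. It was described by the number of genes with a mean of at least 1 in size and one sign in all 5 arrays, and by the percentile of each list median among 10000 random lists of the same size. The 24 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The preset test and fry used the same units as the tests of genes. The estimated correlation was fitted on single arrays with time means, 10 for starvation and late minus early and 15 between the arms. Time points of a culture then count as separate units, so preset and estimated results differ in more than the correlation. Position was tested by the Spearman correlation of log ratio with distance from the replication origin, counted in genes along the shorter arm, with a two-sided p from all 3486 rotations of the gene order. Near genes lay within 10% and far genes beyond 40% of the gene order. No coordinates were used, because the build of the array is not given in the sources used here, and the planned 20 kb windows became windows of 20 genes.

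Replicate number and dye orientation coincide in starvation. The deviations of same-numbered arrays correlated between all 10 pairs of time points (r from 0.444 to 0.682), so the numbers pair the samples, and counts with the replicate number as a block are printed where they move a count by over 1.5 times. This pairing comes from the values and covers both culture and dye.

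On simulated data with the spread of these 3655 genes, the starvation mean test recovered 0% of genes changed by 0.5 log units, 7.14% of those changed by 1 and 100% of those changed by 2. The late minus early test recovered 5.71% at 1 and 92.6% at 2, and the 90 min test 0% at 1 and 73.5% at 2. The starvation minus limitation test recovered 0% at 0.5, 1 and 2 log units. Camera called 20 of 20 lists shifted by 0.5 and 0 of 460 lists that were not shifted. The simulated genes varied independently, so this does not show how often camera at the preset correlation calls lists whose genes vary together. In these data the estimated correlation ran from 0.0991 for general stress to 0.915 for flagella and chemotaxis. It was estimated on the starvation arrays as deposited, which keep the offset between the replicates. An offset shared by all genes raises the correlation within any list, and how far it did so here was not tested. A call lost with the estimated correlation therefore does not show that the genes of that list vary together. The number of arrays limits the precision. So does the offset between the starvation replicates, whose all-gene medians were 0.23 and -0.39 and which stays in the deposited values. With the replicate block, which takes up this offset and any other difference between the replicates, the 90 min test recovered 30% at 1 log unit. The simulated replicates differed by array offsets, a dye effect and noise, with no effect of culture. The simulation therefore does not show how often the block calls genes that differ between cultures. No spot intensities were analysed here.

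Genes were named by a rule fixed before the data were examined. It took the 10 largest starvation rises and 10 largest falls that passed and had one sign in all 10 arrays, filled by smallest p where fewer passed. It took the 6 largest late minus early changes each way, the 6 largest starvation minus limitation differences each way, the 8 largest limitation means each way with one sign in all 5 arrays, 12 fixed genes, and up to 4 members of each list. Alternatives were median centring, scaling to one spread, a filter on noisy genes (75% of genes kept), robust eBayes, the replicate block, other units of replication, and each replicate or time left out. All rows with the repeating ones, the tests of lists between starvation and limitation, centring together with the block, fits without the 15 min arrays, and the late minus early lists with a block or with 1 replicate were added after the data were examined.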

Results

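The data describe how transcript levels in a thymine-requiring strain of Escherichia coli moved after thymine was withdrawn or made limiting. There were 10 starvation arrays, 5 from each of 2 biological replicates, and 5 limitation arrays from 1 replicate, covering 15, 30, 45, 60 and 90 min. Each value is a log ratio of shifted over unshifted RNA of one array, and 3655 genes were used. The strain is thyA- in both RNA pools of every array, so the thyA ratio does not check the labels. Its mean was -0.09 ± 0.85 (SD, n = 2) in starvation, or 0.00 with median centring, and -0.02 in limitation.

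The first comparison asked which transcripts differed from the unshifted culture over the whole starvation course. Genes of the SOS response, the LexA-controlled response to DNA damage, were among the largest rises. recN, a recombination repair gene, rose by 2.63 ± 0.17 log units (SD, n = 2, adjusted p = 4.95e-12), and sulA, an inhibitor of cell division, by 2.20 ± 0.04 (adjusted p = 1.82e-08). recA, the recombinase that activates the response, rose by 1.39 ± 0.12 (adjusted p = 0.00543), and lexA, its repressor, by 1.38 ± 0.21 (adjusted p = 0.00552). umuC, a subunit of a translesion polymerase, rose by 1.28 ± 0.18 and uvrA, of nucleotide excision repair, by 1.27 ± 0.06. These 6 genes lay above 0 in 10 of 10 arrays. yebG rose by 1.48 ± 0.29 and lay above 0 in 9 of 10. With robust eBayes recN and sulA passed, and the other 5 did not, with recA and lexA at an adjusted p = 0.201.

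Outside the SOS list, deoC, deoxyribose-phosphate aldolase, rose by 1.45 ± 0.37 (SD, n = 2, adjusted p = 0.00285) and dkgA, a reductase, by 1.42 ± 0.20 (adjusted p = 0.00361), both in 10 of 10 arrays. zinT, which encodes a periplasmic zinc-binding protein, rose by 1.60 ± 0.11 and lay above 0 in 7 of 10 arrays. Its call was lost without the 60 min arrays (adjusted p = 0.288) or the 90 min arrays (adjusted p = 0.149). sufB, of iron-sulphur cluster assembly, rose by 1.43 ± 0.20, dps, which encodes a DNA-binding ferritin-like protein, by 1.29 ± 0.32, and fepA, an outer membrane receptor for ferric enterobactin, by 1.24 ± 0.02. With robust eBayes none of these 6 genes passed, and the lowest was zinT at an adjusted p = 0.0566.

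The largest falls were in genes of pyrimidine synthesis and uracil and cytosine uptake. uraA, the uracil permease, had a mean of -2.44 ± 0.03 (SD, n = 2, adjusted p = 2.29e-10) and codB, the cytosine permease, -2.06 ± 0.09 (adjusted p = 2.53e-07), both below 0 in 10 of 10 arrays. pyrI and pyrB, the subunits of aspartate carbamoyltransferase, stood at -2.39 ± 0.05 and -2.31 ± 0.13, and their neighbour ridA at -1.98 ± 0.11, each below 0 in 9 of 10 arrays. The succinate dehydrogenase genes sdhD and sdhC also fell, with means of -1.38 ± 0.05 and -1.17 ± 0.16, as did the outer membrane protease gene ompT (-1.35 ± 0.16), the nucleoid protein gene hns (-1.33 ± 0.08) and the galactitol transport gene gatB (-1.20 ± 0.08), each in 10 of 10 arrays.

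In all, 31 of 3655 genes passed limma's test on the 2 culture means, 15 above and 16 below 0. With each array centred on its median, 126 passed, 83 above and 43 below, and all 31 were among them. With the 10 arrays as units and the replicate block, 467 passed, 155 above and 312 below. This count takes time points of the same 2 cultures as separate units and leaves the difference between cultures out of the spread. With robust eBayes 8 passed. These 8, all among the 31, were recN and sulA above 0 and uraA, codB, codA, pyrI, pyrB and ridA below, so 13 of the 15 rises and 10 of the 16 falls lost their call under that setting. Leaving out the 15 min arrays gave 63 genes and leaving out the 60 min arrays 12.

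**Figure D1:**
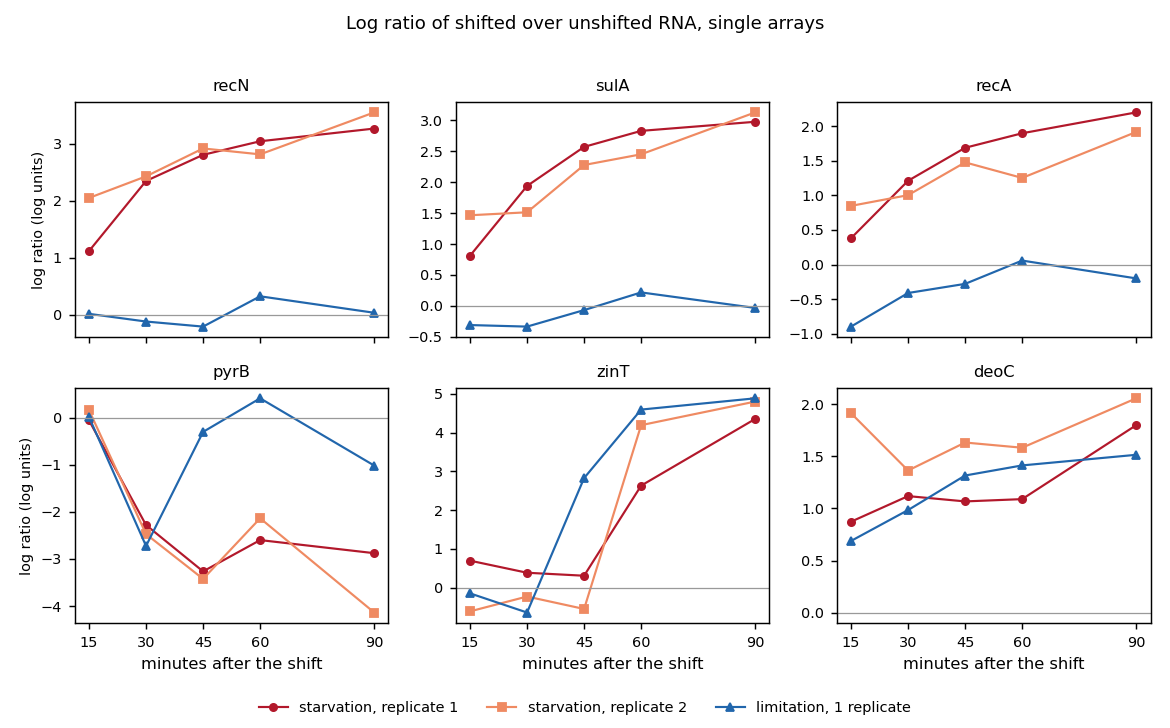
Log ratio of shifted over unshifted RNA (log units, vertical axes, which differ in range) against minutes after the shift for 6 genes, with 1 point per array and a line per culture (starvation replicates 1 and 2, limitation 1 replicate). The starvation means over 5 times are 2.63 for recN, 2.20 for sulA, 1.39 for recA and -2.31 for pyrB, while the limitation means are 0.01, -0.11, -0.35 and -0.72. The zinT curves turn upward after 30 to 45 min in all 3 cultures.

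The 24 gene lists were compared with all other genes in the same 2 culture means. In the SOS list, 7 of 28 measured genes rose and 0 fell, and 12 rose when adjusted over the list alone. Its median was 0.55 (camera adjusted p = 1.58e-51, and adjusted p = 0.0861 with an estimated correlation). The other members of the fixed set, dinI at 0.95 ± 0.19 (SD, n = 2) and umuD at 0.88 ± 0.26, did not pass (adjusted p = 0.254 and 0.435). The general stress list of sigma S had a median of 0.77, with 2 of 21 genes risen, dps and tktB, a transketolase (1.16 ± 0.29), and 12 when adjusted over the list alone. Its camera adjusted p was 6.72e-35, and it was the 1 list still called with an estimated correlation (adjusted p = 0.0110). That call takes time points of the same 2 cultures as separate units.

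In the pyrimidine synthesis list, 5 of 12 genes fell, namely pyrI, pyrB, carA (-1.58 ± 0.28), carB (-1.46 ± 0.40) and pyrC (-1.33 ± 0.62), and 6 when adjusted over the list alone. The list median was -0.83 (camera adjusted p = 2.95e-32, and adjusted p = 0.113 with an estimated correlation). In the TCA cycle list 3 of 13 genes fell, sdhD, sdhC and sdhA (-1.23 ± 0.04), and 6 when adjusted over the list alone, with a median of -0.72 (camera adjusted p = 1.33e-14, and adjusted p = 0.113 with an estimated correlation). The ATP synthase list had a median of -0.68 and the ribosomal protein list one of -0.32, with 0 of 8 and 0 of 45 genes past the threshold over all genes and 0 adjusted over the list alone in both. Their camera adjusted p were 7.59e-09 and 2.72e-06 (adjusted p = 0.113 and 0.351 with an estimated correlation). Less the median of all genes, the ribosomal protein list stood at -0.55 in replicate 1 and 0.03 in replicate 2, so its position against other genes comes from replicate 1, while ATP synthase stood at -0.88 and -0.34. The atpE and atpD genes stood at -0.80 ± 0.22 and -0.79 ± 0.05, and rpsN at -0.64 ± 0.13.

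In the deoxyribonucleoside list 1 of 12 genes rose, deoC, while deoA stood at 1.15 ± 0.04 (adjusted p = 0.050) and deoD at 0.94 ± 0.31. Adjusted over the list alone, 3 rose and 1 fell. Its median was -0.09 although camera placed the list above other genes (adjusted p = 0.000693, and adjusted p = 0.266 with an estimated correlation). In the oxidative stress list 1 of 22 genes rose, sufB, and 4 when adjusted over the list alone (median 0.11, camera adjusted p = 5.52e-08, and adjusted p = 0.258 with an estimated correlation). In the iron uptake list 1 of 28 rose, fepA, and 2 when adjusted over the list alone (median 0.20, camera adjusted p = 1.77e-13, and adjusted p = 0.266 with an estimated correlation). The ribonucleotide reductase list had 0 of 9 genes past the threshold and 1 risen when adjusted over the list alone (median 0.27, camera adjusted p = 3.25e-05, and adjusted p = 0.266 with an estimated correlation). Here nrdB stood at 0.79 ± 0.02 and nrdA at -0.00 ± 0.62, or 0.09 with median centring.

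No single gene passed in 5 further called lists. Acid resistance had a median of 0.33 over 11 genes, with 2 risen when adjusted over the list alone (camera adjusted p = 5.21e-07, and adjusted p = 0.258 with an estimated correlation). Heat shock had a median of 0.13 over 15 genes (camera adjusted p = 0.00902), and histidine, branched-chain and tryptophan synthesis one of 0.12 over 21 (camera adjusted p = 0.000422). Purine synthesis had a median of -0.39 over 12 genes (camera adjusted p = 0.00491), and arginine and methionine synthesis one of -0.21 over 16 (camera adjusted p = 0.0204). With an estimated correlation these 4 had an adjusted p = 0.392, 0.392, 0.392 and 0.474, and 0 of their genes passed when adjusted over the list alone. The replicates did not agree on these 4. Less the median of all genes, replicates 1 and 2 stood at -0.08 and 0.44 for heat shock, -0.21 and 0.64 for histidine, branched-chain and tryptophan synthesis, -0.58 and 0.01 for purine synthesis, and -0.44 and 0.15 for arginine and methionine synthesis, so each call comes from 1 culture. The oxidative stress list (-0.05 and 0.48) and the deoxyribonucleoside list (-0.01 and 0.17) also differed in sign.

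The remaining 9 lists did not pass camera, and 0 of their genes passed over all genes or adjusted over the list alone. Their medians were -0.09 for DNA repair outside the SOS list (adjusted p = 0.911), -0.04 for DNA replication (0.665), -0.09 for thymidylate and folate metabolism (0.673), -0.05 for flagella and chemotaxis (0.947), -0.11 for cell division (0.360), -0.23 for phage shock (0.328), -0.00 for the e14 prophage (0.113), -0.09 for the Rac prophage (0.925) and -0.13 for cold shock (0.253). Of these, dnaA stood at 0.20 ± 0.03 (SD, n = 2) and gyrB at -0.09 ± 0.04, and the sign of gyrB turned to 0.00 with median centring.

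**Figure D2:**
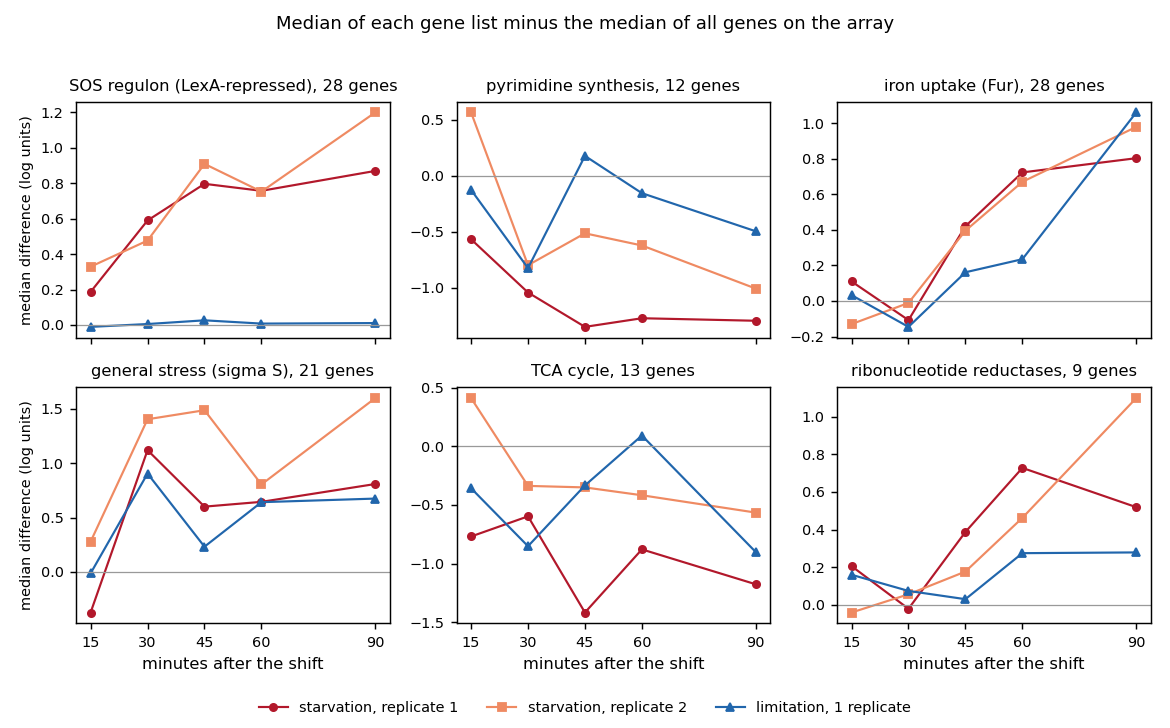
Median log ratio of the measured members of 6 gene lists minus the median of all genes on the same array (log units, vertical axes, which differ in range) against minutes after the shift, with 1 point per array and a line per culture. In the SOS panel the list medians over the course, less the median of all genes, are 0.58 and 0.69 in the starvation replicates and 0.01 in limitation, and the iron uptake panel rises in all 3 cultures.

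Single starvation times asked when these changes could first be seen. At 15 min 0 genes passed limma's test (49 at an unadjusted p under 0.05), with recN at 1.58 and sulA at 1.14. The replicates correlated at r = -0.343 over genes at this time. The deposited replicate 1 arrays held 399 (15 min) to 451 (90 min) values printed with the last zero dropped, and the other arrays 0. With the repeating rows, this marks the 15 min array of replicate 1 as turned like its other times. Whether that turn was right at 15 min was not tested, and the 15 min values depend on it. At 30 min 21 genes passed, 10 above and 11 below 0, including recN (2.39, adjusted p = 0.00316), sulA (1.73, adjusted p = 0.0192), uraA (-2.78, adjusted p = 0.00316) and pyrB (-2.38, adjusted p = 0.00481). At 45 min 16 passed, 6 above and 10 below, and recA was then past the threshold at 1.58 (adjusted p = 0.0437). At 60 min 31 passed, 17 above and 14 below, with zinT at 3.41 (adjusted p = 0.000650) and fepA at 2.72. At 90 min 90 passed, 66 above and 24 below, with recN at 3.41, zinT at 4.58 and pyrI at -3.92 (adjusted p = 3.02e-05 for each), and all 31 genes of the 60 min set were among them.

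With the replicate block, limma called 9, 100, 116, 141 and 221 genes at 15, 30, 45, 60 and 90 min, split into 3 above and 6 below 0, 62 and 38, 50 and 66, 62 and 79, and 141 and 80. Counts with the block take arrays of the same 2 cultures as separate units and leave the difference between the cultures out of the spread. Centring moved the split of higher and lower genes to 22 and 5 at 30 min, 10 and 6 at 45 min and 38 and 10 at 60 min, and scaling to 138 and 31, 12 and 5, and 48 and 12. Centring with the block gave 5 and 27 at 15 min, 166 and 53 at 30 min, 117 and 64 at 45 min, 94 and 172 at 60 min and 245 and 131 at 90 min, so at 30, 45 and 60 min the larger side depends on the setting, and the median of all genes before centring was -0.15 at 30 min and -0.18 at 45 min. Without replicate 1 of the tested time the counts at 30, 45, 60 and 90 min were 0, 6, 1 and 49, and without replicate 2 of that time they were 0, 11, 0 and 41. These fits keep the other 9 arrays, 1 of them at the tested time, and take the spread from the 4 other times.

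Late (60 and 90 min) minus early (15 and 30 min) starvation arrays asked which transcripts moved on during the course. The 6 largest increases were those of zinT, fepA, znuA, fhuF, entB and mepM. zinT rose by 3.94 ± 0.38 log units (SE, 4 and 4 arrays, adjusted p = 6.60e-11) and znuA, the binding protein of the zinc transporter, by 2.59 ± 0.33 (adjusted p = 3.39e-07). fepA rose by 2.75 ± 0.33 (adjusted p = 9.14e-08), fhuF, a ferric reductase, by 2.40 ± 0.35 (adjusted p = 4.86e-06) and entB, of enterobactin synthesis, by 2.28 ± 0.34 (adjusted p = 8.57e-06). mepM, a peptidoglycan hydrolase encoded beside znuA, rose by 2.25 ± 0.35.

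The largest decreases were pyrI at -1.82 ± 0.43 (SE, adjusted p = 0.0139) and pyrB at -1.77 ± 0.43 (adjusted p = 0.0147). Next were the iron superoxide dismutase gene sodB (-1.60 ± 0.35, adjusted p = 0.00446) and ridA (-1.60 ± 0.40). Then came bfr, which encodes bacterioferritin (-1.57 ± 0.34), and oppB, of oligopeptide uptake (-1.50 ± 0.34). In all 40 genes passed, 32 above and 8 below 0, and 85 with the replicate block, 55 above and 30 below. Centring gave 34 above and 3 below, scaling 32 and 1, and centring with the block 35 and 29.

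Among the lists, 12 of 28 iron uptake genes rose late, and 16 when adjusted over the list alone (median 0.98, camera adjusted p = 2.27e-47, and adjusted p = 0.146 with an estimated correlation). In the oxidative stress list 5 of 22 rose, the suf genes sufA, sufB, sufC, sufD and sufS, and 7 when adjusted over the list alone (camera adjusted p = 4.65e-08, and adjusted p = 0.223 with an estimated correlation). In the SOS list 3 of 28 rose, sulA (1.41 ± 0.34), umuC (1.55 ± 0.34) and yebG (1.49 ± 0.36), and 6 when adjusted over the list alone (camera adjusted p = 1.81e-16, and adjusted p = 0.146 with an estimated correlation). In the ribonucleotide reductase list 3 of 9 rose, nrdH (2.06 ± 0.34), nrdI (1.57 ± 0.36) and nrdB (1.30 ± 0.34), and 4 when adjusted over the list alone (camera adjusted p = 2.32e-11, and adjusted p = 0.146 with an estimated correlation). Of the pyrimidine list 2 of 12 fell, and 2 when adjusted over the list alone (camera adjusted p = 1.39e-10, and adjusted p = 0.146 with an estimated correlation).

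No member passed over all genes in the other 7 called lists. General stress (median 0.42, camera adjusted p = 2.19e-05), acid resistance (0.47, 0.00630) and the e14 prophage (0.51, 3.43e-08) were higher late, with 0, 0 and 2 genes when adjusted over the list alone. TCA cycle (-0.43, 1.97e-11), ATP synthase (-0.42, 4.26e-05), ribosomal proteins (-0.18, 0.000571) and cold shock (-0.21, 0.000571) were lower late, with 4, 0, 0 and 1. With an estimated correlation 0 lists were called, and the smallest was adjusted p = 0.146. The other 12 lists did not pass camera, with adjusted p from 0.0899 for heat shock to 0.917 for phage shock.

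The limitation culture was described without a test. Its largest means with one sign in 5 of 5 arrays were pliG, a lysozyme inhibitor gene (1.40), hdeB, of the acid stress chaperones (1.36), nrdH, which encodes a glutaredoxin-like electron donor (1.27), msyB (1.21), deoC (1.18), sra (1.04), dkgA (1.02) and pheA, of phenylalanine synthesis (0.96). The lowest were uraA (-1.61), codB (-1.11), rplF (-0.91), gatC (-0.89), atpA (-0.88), nuoN (-0.85), ptsG, the glucose transporter gene (-0.85), and lpp (-0.82). The SOS genes recN, sulA, recA and lexA stood at 0.01, -0.11, -0.35 and -0.12.

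By size, 9 genes had a limitation mean of at least 1 with one sign in all 5 arrays, 7 above and 2 below 0. The same count was 60 in starvation replicate 1 (27 above, 33 below) and 23 in replicate 2 (15 above, 8 below). Without the 15 min array the limitation count was 21, and without the 45 min array 16. The SOS list median was -0.08 in limitation, at percentile 58.3 of random lists. General stress (0.34), oxidative stress (0.24), iron uptake (0.16) and histidine, branched-chain and tryptophan synthesis (0.20) lay at percentile 100, and pyrimidine synthesis (-0.42), TCA cycle (-0.56), ATP synthase (-0.56) and ribosomal proteins (-0.30) at percentile 0. The random lists drew genes singly, while genes of one list may move together, so an extreme percentile is not a test. It describes 1 culture with 1 dye orientation.

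Starvation minus limitation asked which genes responded to the absence of thymine beyond its shortage. recN was the 1 gene of 3655 past limma's threshold, higher in starvation by 2.63 log units (mean 2.63 in starvation and 0.01 in limitation, adjusted p = 0.0145). sulA was 2.30 higher, with an adjusted p = 0.0952. Differences were 1.73 for recA, 1.49 for lexA, -1.58 for pyrB and -1.66 for ompT. On simulated data this test recovered 0% of genes changed by 1 or 2 log units. Not passing it at these sizes is therefore no evidence that the arms were alike. Centring gave 6 genes, the 15 arrays with 10 group means 8, and robust eBayes 0 (14 genes had an unadjusted p under 0.05 in the main test). The limitation side rests on 1 culture, with 1 dye orientation, which is assumed to vary like the 2 starvation cultures. The estimated prior degrees of freedom were infinite in this fit too, so all genes shared 1 spread and that of recN itself played no part. The call of recN holds only under both conditions.

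Distance from the replication origin was examined because thymine is needed for DNA synthesis. Over genes, which are not independent replicates, the starvation mean had a Spearman rho of 0.0394 with distance (rotation p = 0.0393, two-sided) and limitation one of 0.0578 (p = 0.0402). The 664 genes near the origin had a median of -0.09 and the 713 far genes one of -0.07 in starvation, against -0.10 and -0.06 in limitation. Replicate 1 of starvation alone gave a rho of 0.101 and replicate 2 one of -0.0370, so the direction differed between replicates. Of the 15 arrays taken singly, the lowest adjusted p was 0.118. Without the SOS, ribosomal protein and ATP synthase lists the p was 0.113 in starvation and 0.0881 in limitation. With 1 median per window of 20 genes the rho was 0.0872 (p = 0.0172) in starvation and 0.127 (p = 0.00858) in limitation, and without noisy genes it was 0.0876 (p = 0.0110) in limitation.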

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

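All tests of explanations in this part were chosen after the results they bear on had been seen, and so was the camera test of lists between starvation and limitation.

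The difference between the arms was past limma's threshold for recN, at 2.63, with the lone limitation culture assumed to vary like the starvation cultures, and robust eBayes called 0 genes. By camera with the preset correlation, the arms also differed in 10 lists. The median differences, starvation minus limitation, were 0.66 for the SOS list, -0.53 for pyrimidine synthesis, -0.16 for purine synthesis, 0.23 for heat shock, 0.28 for general stress, 0.13 for flagella and chemotaxis, 0.14 for iron uptake, -0.35 for arginine and methionine synthesis, -0.21 for the TCA cycle and 0.13 for the e14 prophage. With an estimated correlation 0 of these were called, and the smallest was adjusted p = 0.0926, for the SOS list. Less the all-gene median, replicates 1 and 2 stood at -0.99 and -0.32 for the TCA cycle. They stood at -0.58 and 0.01 for purine, and -0.44 and 0.15 for arginine and methionine synthesis. Limitation medians as deposited were -0.56, -0.13 and 0.03, with all genes at -0.08. Against all genes, replicate 2, of the same dye orientation, thus lay above limitation in each, opposite to the printed difference. In the other lists both replicates went with it, heat shock barely in replicate 1. dinB and dinI, both SOS genes, lay above 0 in 10 of 10 starvation arrays and below 0 in 5 of 5 limitation arrays, with differences of 0.97 and 1.24. They were picked for this opposition of signs. limma's test of the difference was not passed by either, but on simulated data it recovered 0% of genes changed by 1 or 2 log units.

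The first pattern is the SOS response, high in starvation and near 0 in limitation. A weaker response of every gene in limitation is argued against, because the 8 other genes that rose in starvation had a limitation mean of 1.03 ± 0.55 (SD over genes) against -0.04 ± 0.19 for the 7 risen SOS genes, a gap of 1.07 (exact permutation p = 0.000311 over 6435 assignments, two-sided). A dye bias of the SOS genes, shared by arrays of one orientation, is argued against as well, since starvation replicate 2 and limitation have the same dye orientation and their median difference over the list, less the medians of all genes, was 0.83 (95% bootstrap interval over genes 0.50 to 1.23), above 0 for 27 of 28 genes. The permutation and the bootstrap take genes as independent units, which genes of one regulon are not. Neither measures a spread between cultures, so both describe these genes in these cultures only. With 1 limitation culture, an unusual culture cannot be told apart from an effect of residual thymine. A response to full withdrawal of thymine therefore remains a hypothesis.

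The second pattern is the low level of pyrimidine and uracil genes in starvation. Washing and moving the cells, common to both arms, may have contributed, since the 8 fallen genes of this kind had a median, less that of all genes, of -0.73 in limitation against -2.29 and -1.44 in the starvation replicates. The gap of 0.71 to the nearer replicate is smaller than the 0.86 between the replicates, but on the deposited values the medians were -0.82 in limitation and -2.07 and -1.83 in starvation, a gap of 1.01 against 0.24 between the replicates. Because the comparison turns with the subtraction of the median of all genes, and limitation is 1 culture, a handling effect and a thymine effect cannot be told apart from these medians. pyrB stood at -2.28 and -2.47 in starvation and -2.73 in limitation at 30 min, and at -2.60 and -2.14 in starvation and 0.41 in limitation at 60 min. At 90 min it stood at -2.88 and -4.14 in starvation and -1.02 in limitation.

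The third pattern is the difference between the starvation replicates, which correlate at -0.343 at 15 min. Over genes, replicate 2 minus replicate 1 correlated with the limitation mean, which has the dye orientation of replicate 2, at r = 0.312. A gene-specific dye bias could give this, but r ranged from -0.185 to 0.517 over single limitation arrays, so it stays open. A difference between the 2 cultures cannot be told apart from it, because 0 of the starvation replicates have both dye orientations. Whether limitation and replicate 2 share unshifted RNA is not given in the sources used here.

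For late minus early, 3 of the 35 splits of the 8 arrays into 4 and 4 called at least the 40 genes of the real split, so chance is not excluded by this count. The highest other count was 1690, from the split that parts replicate 1 from replicate 2, which points to a structure of the samples by culture or dye. Among the 18 splits with 2 arrays of each replicate on each side, the real one called 40 genes and the highest other 1, but 18 splits are too few for a share under 5%.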

How the results depend on the processing

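Of the alternatives here, those with all rows, with centring and the block together, without the 15 min arrays for starvation minus limitation and for lists in starvation, all on lists between the arms, and those on late minus early lists with the block or without 1 replicate were chosen after the data were examined. The comparisons with complete genes and with single rows had nothing to change in this table and were not run. Where a count moved, the cause was not tested, except that dropping a replicate leaves fewer arrays and a noise filter fewer genes.

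Against 31 genes for the starvation mean, median centring called 126, scaling to one spread 129, the filter on noisy genes 73, robust eBayes 8, 10 arrays with 5 time means 180, and these with the replicate block 467. The counts of 180 and 467 take time points of the same culture as separate units. Leaving out 1 time gave 12 (without 60 min) to 63 genes (without 15 min). With the replicate block the counts at 15, 30, 45, 60 and 90 min were 9, 100, 116, 141 and 221, and with centring and the block 32, 219, 181, 266 and 376. Counts with the block leave the difference between the cultures out of the spread. Centring alone gave 48 at 60 min, scaling 169 at 30 min and 60 at 60 min, the noise filter 1, 55, 48 and 74 at 15 to 60 min, and all rows 9 at 45 min. Without 1 replicate of the tested time, with the spread taken from the 4 other times, 0 genes were called at 30 min, 6 to 11 at 45 min, 0 to 1 at 60 min and 41 to 49 at 90 min. Late minus early gave 85 with the replicate block, 64 with centring and the block, 25 from 10 arrays, and 33 to 43 without 1 replicate. The block changed no call count of the lists, which stayed at 12.

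Starvation minus limitation called 6 genes with centring, 3 with scaling, 2 with the noise filter, 0 with robust eBayes, 8 from 15 arrays and 2 without the 15 min arrays. Genes of size in limitation numbered 14 with centring and 15 with scaling, and 6 (without 90 min) to 21 (without 15 min) with 1 time left out. With an estimated correlation, fitted on single arrays, 1 list was called in starvation, 0 late minus early and 0 between the arms. fry called 2 (purine, and arginine and methionine synthesis) and 0. Between the arms all rows gave 6 lists.

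The rho of distance from the origin was 0.0281 with all rows (p = 0.0808) and 0.0208 without the 3 lists in starvation, 0.0448 without them in limitation, 0.0872 and 0.127 with windows of 20 genes in starvation and limitation, 0.0876 without noisy genes in limitation, and -0.0370 to 0.101 without 1 starvation replicate. Signs near 0 turned. With centring thyA became 0.0037, nrdA 0.0914 and gyrB 0.0048, and with scaling nrdA became 0.0782 and gyrB 0.0106. With 1 time left out nrdA ranged from -0.0639 to 0.0379 and the e14 gene ymfJ from -0.128 to 0.426. Late minus early with 1 replicate left out, flgJ ranged from -0.047 to 0.923 and pspF from -0.0185 to 0.552. Turning the sign of the deposited ratios would turn the SOS median to -0.55. For single genes and lists, 2361 other values kept their direction and side of the threshold (or moved by less than their spread), 158 kept direction and lost the call, and 197 gained one.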

Other observations

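The values in this part were looked up after the late minus early result had been seen, and no test was run on them. The iron uptake list had a median late minus early value of 0.78 in limitation, against 0.27 for all genes. Other lists came close, with 0.75 for histidine, branched-chain and tryptophan synthesis and 0.73 for heat shock. Cold shock and ATP synthase, which were lower late in starvation, both had 0.68, so a high value was not particular to iron uptake. zinT went from -0.40 at 15 and 30 min to 4.74 at 60 and 90 min in limitation, a difference of 5.14, and znuA and mepM differed by 2.66 and 3.03. The iron genes fepA, fhuF, entB and tonB differed by 2.57, 2.84, 2.06 and 2.07. Of the 32 genes that rose late in starvation, 31 had a late minus early value above 0 in limitation, where 78.6% of all genes did, and 26 had one of at least 1.

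Of the 6 late risers under 1 in limitation, 3 were SOS genes. sulA, umuC and yebG had limitation differences of 0.41, 0.21 and 0.23, close to the median of all genes, and nrdB, a subunit of the aerobic ribonucleotide reductase, one of -0.04. The iron-sulphur assembly genes sufS and sufC had 0.90 and 0.655, while nrdH and nrdI, of the manganese-dependent enzyme, had 1.98 and 1.62. Of the 8 genes that fell late in starvation, 2 were below 0 in limitation, sodB at -1.17 and bfr at -0.49. pyrB, pyrI and ridA went the other way, at 1.05, 0.91 and 0.97, and oppB, oppD and fdoG, a formate dehydrogenase gene, stood at 0.39, 0.34 and 0.30.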
